A study of Mus musculus with 4 samples.

How the data were processed

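Polyadenylated RNA of brown adipose tissue from WT and Ebf2 KO mice aged 8 weeks was sequenced as 4 libraries, 2 per genotype, per the labels. Per the labels, the mice had a mixed strain background and were kept on chow at room temperature. The libraries were made with an Illumina TruSeq kit, per the labels. The authors aligned the reads with STAR and compared the genotypes with edgeR on the mm9 build, per the submitters' processing notes. The versions, the counting tool, the gene annotation and the strand setting are not given in the sources used here. The authors deposited 1 table of 12165 genes with an RPKM per library and the mean RPKM of each genotype, per the file headers. It also holds the authors' log2 fold change of KO over WT, an average log2 CPM, a p-value and an FDR per gene, per the file headers. Each gene listed reached at least 0.5 RPKM in at least 1 library, and the deposited FDR equalled the Benjamini-Hochberg adjustment of the deposited p-values over the listed genes. The log2 ratio of mean RPKM exceeded the authors' deposited log2 fold change by a median of 0.638 (SD 0.0282 over 9290 genes with a mean RPKM of at least 1). The authors thus scaled the libraries in another way for their test than for the RPKM values. A reference of the mm9 build was not used here, and no coordinates are given; 11613 of the 12165 symbols were found in GENCODE M21.

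The depth was worked out from the RPKM values. RPKM of short genes with few reads are whole multiples of what 1 read is worth, and 184 microRNA genes of known length gave the library totals (199678916 and 176574890 reads in WT replicates 1 and 2, 176568920 and 162782640 in Ebf2 KO replicates 1 and 2). With these totals the values of 12165 genes (100%) came out as whole reads in all 4 libraries within 1e-06 reads. The listed genes held 86224535, 80131132, 104240043 and 100480072 of these reads in the same order, so the RPKM denominator counts reads outside the listed genes. No library repeated another: the chi-square per gene between replicates was 419.2 in WT and 429.8 in Ebf2 KO, far above sampling noise.

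Groups were taken from the labels. The unit called for a test on a log scale: limma with a variance trend was fitted to log2(RPKM + 1) of all 4 libraries with genotype as the 1 term, and p-values were adjusted by the Benjamini-Hochberg method over the 12165 genes, with a threshold of 0.05. Log2 fold changes on this scale understate the change of genes near or below 1 RPKM, whereas fold values in the text are ratios of mean RPKM. Limma's prior had 5.605 degrees of freedom beside 2 residual ones. The test, the lists, the rule for named genes and the alternatives were chosen before the data were examined, except where stated. A count test had been planned for a table of counts and limma for a table of normalized values, which is what was found. The fit was also run on simulated data with a replicate coefficient of variation of 20% and 200 of 12165 genes changed. It recovered 50 of 50 genes at a log2 change of 2 and 50 of 50 at -2. It recovered 21 of 50 at 1 and 24 of 50 at -1, and called 11 of 11965 unchanged genes. The simulated values held no shift of most genes between the groups, unlike the RPKM values. These counts thus do not cover calls that such a shift brings.

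Ebf2 was reported first. The genes named next were the 10 largest log2 changes each way among genes past the threshold with a mean of at least 5 RPKM and no overlap between groups. Added to these were up to 4 members per list with the smallest p (or the 2 most abundant members where none passed). A fixed set of Ucp1, Cidea, Ppargc1a, Prdm16, Ppara, Dio2, Lep, Adipoq, Pparg, Fabp4 and Ebf1 was always named. Gene models without a proper name were passed over. This gave 97 genes, some of which are not reported here. There were 24 gene lists: brown fat and thermogenic genes, white fat-enriched genes, general adipocyte genes, fatty acid oxidation, respiratory chain subunits, the tricarboxylic acid cycle, fatty acid synthesis, glycolysis, PPAR alpha targets, the BAF complex, other EBF and zinc finger family members, macrophage, lymphocyte, endothelial, smooth muscle, skeletal muscle, fibroblast, Schwann cell, erythroid and epithelial markers, immediate early and heat shock genes, interferon-stimulated genes, circadian clock genes and sex-linked genes. The 21 lists with at least 5 measured members were tested against all other genes with camera, 2-sided, at a preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were run beside it.

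Alternatives chosen in advance were quantile normalization, median centring, no variance trend, a minimum mean of 5 RPKM, a pseudocount of 0.1, the replicate number as a block, leaving out each library, an adjusted p under 0.01, a minimum absolute log2 fold change of 1 and the authors' deposited values. Alternatives chosen after seeing the data were limma-voom on the recovered reads with median-ratio scaling, median centring combined with the block, with each left-out library or with the minimum fold change, fry on centred values, and list counts without Ebf2 KO replicate 2. The versions were R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.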

Results

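Brown adipose tissue was taken from adult mice aged 8 weeks that were wild type (WT, 2 libraries) or lacked Ebf2 (Ebf2 KO, 2 libraries). Brown fat is the heat-producing form of adipose tissue, and EBF2 is a transcription factor of the early B-cell factor family that is present in brown fat cells and their precursors. The mice were kept on chow at room temperature, and polyadenylated RNA was sequenced. Expression was given as RPKM (reads per kilobase of gene, scaled to the library total) for 12165 genes. The library totals behind the RPKM values were 199678916 and 176574890 reads in WT replicates 1 and 2, and 176568920 and 162782640 reads in Ebf2 KO replicates 1 and 2. At this depth 1 read in a gene of 1 kb was worth between 0.00501 and 0.00614 RPKM, so counting error was small beside the differences between libraries for nearly all genes named here. The listed genes held 43.2% and 45.4% of the library total in the WT libraries and 59.0% and 61.7% in the Ebf2 KO libraries. This difference bears on every comparison of RPKM between the genotypes. Across genes, log2(RPKM + 1) correlated at r = 0.977 between the WT libraries, at 0.982 between the Ebf2 KO libraries and at 0.909 to 0.932 between libraries of different genotype. Genes are not independent replicates.

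Ebf2 itself was measured first. Its RPKM was 2.97 and 2.63 in the WT libraries and 0.391 and 0.352 in the Ebf2 KO libraries, from 3279, 2569, 382 and 317 reads. The mean of 2.80 ± 0.239 (SD, n = 2) in WT was 7.53 times that of 0.372 ± 0.0276 (SD, n = 2) in Ebf2 KO. On the log2(RPKM + 1) scale, which understates the change of a gene at this level, Ebf2 fell by 1.47 (SE 0.208, limma adjusted p = 0.00536). Both libraries labelled Ebf2 KO thus held less Ebf2 RNA than both labelled WT. Which part of the gene was deleted is not given in the sources used here, so the origin of the remaining reads is open.

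The X-linked Xist, which is transcribed from the inactive X chromosome of female cells, was at 5.05 and 6.19 RPKM in the WT libraries, at 5.49 in Ebf2 KO replicate 1 and at 0.0353 in Ebf2 KO replicate 2. The Y-linked genes of the list were not analysed here, and the labels do not give the sex of the mice. Xist was the 1 member of the sex-linked list measured, and its difference between the groups did not pass the threshold (limma adjusted p = 0.177), though it did with any library but Ebf2 KO replicate 2 left out (0.00105 to 0.0260). Counts without Ebf2 KO replicate 2 are given with most groups below.

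The comparison of Ebf2 KO with WT asks which genes need Ebf2 for their normal level in brown fat. Ucp1, the uncoupling protein that makes brown fat produce heat, fell most of all genes named. It stood at 5018 and 5733 RPKM in the WT libraries and at 7.39 and 2.86 in the Ebf2 KO libraries, a 1049-fold lower mean. Cidea, a lipid droplet protein of brown fat, fell 41.8-fold, from 1405 ± 67.4 to 33.7 ± 42.2 RPKM (SD, n = 2 each), and Dio2, the deiodinase that activates thyroid hormone, fell 266-fold. In the other direction, the white fat hormones leptin (Lep) and resistin (Retn) rose 17.7-fold and 12.1-fold. Fabp4, a fatty acid carrier of fat cells, was at 14910 ± 3572 RPKM in WT and 24054 ± 1659 RPKM in Ebf2 KO. Both Ebf2 KO values lay above both WT values, but the difference did not pass the threshold (limma adjusted p = 0.369). In the authors' deposited table the log2 fold change of Fabp4 was 0.02 (edgeR FDR 0.981). Over all 12165 genes, 2971 were higher and 431 were lower in Ebf2 KO at an adjusted p under 0.05 by limma on log2(RPKM + 1).

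**Figure D1:**
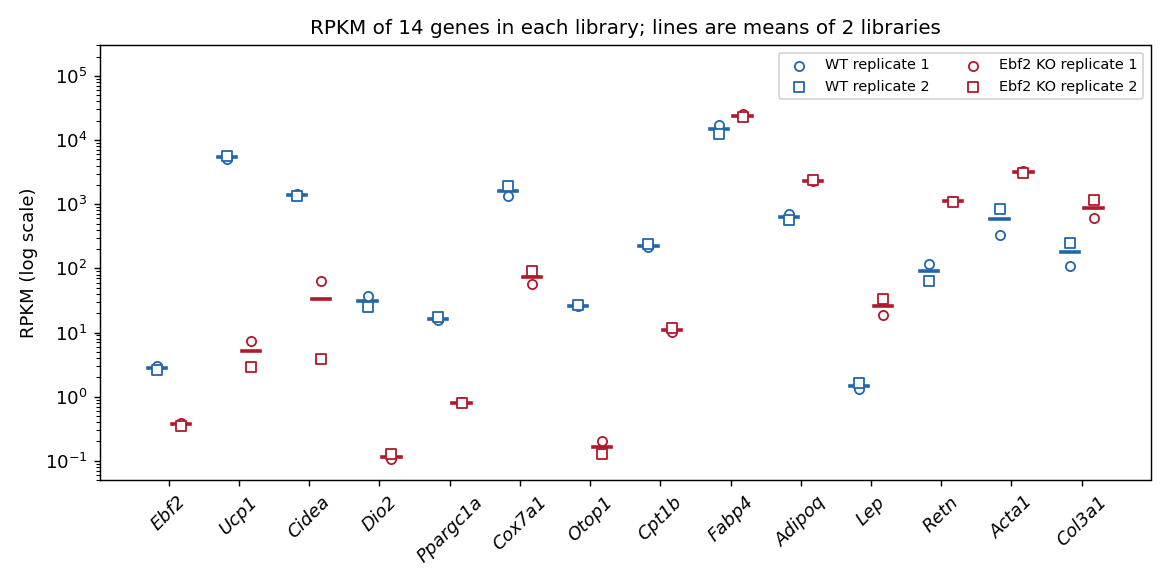
RPKM (log scale) of 14 genes in each of the 4 libraries: open circles are replicate 1, open squares replicate 2, blue is WT, red is Ebf2 KO, and each line is the mean of the 2 libraries of a group. Ucp1, Cidea, Dio2, Ppargc1a, Cox7a1, Otop1 and Cpt1b lay lower in both Ebf2 KO libraries than in both WT libraries, and Lep, Retn, Adipoq, Acta1 and Col3a1 lay higher; Cidea was at 63.5 RPKM in Ebf2 KO replicate 1 and at 3.81 RPKM in replicate 2.

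The excess of higher over lower genes depended on how the libraries were scaled. The median log2 fold change of all genes was 0.45 (1.371-fold) on the log2(RPKM + 1) scale, which understates the shift of low genes. It was 0.63 with a pseudocount of 0.1. Once each library was centred on its median, 1024 genes were higher and 1253 lower, so the higher genes made up 45% of the calls in place of 87.3%. Centring brings the median change near 0 by construction, so this balance does not tell whether the shift is technical or biological. In the authors' deposited table, 1325 genes were higher and 1277 lower at an FDR under 0.05. Of the genes called on RPKM, 1024 higher and 424 lower ones were also called after centring. Of these, 959 and 424 were called in the same direction in the authors' deposited table as well. For this reason each group below is given with its count on RPKM and its count after centring, and each list called by camera also with its median relative to the median of all genes. Single libraries moved these counts. With Ebf2 KO replicate 2 left out, 810 genes were higher and 166 lower on RPKM, and 746 and 727 after centring. Without WT replicate 2 the counts on RPKM were 4477 and 541, and without WT replicate 1 the centred counts were 415 and 578.

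The 10 genes with the largest decrease were Ucp1, Cidea, Gmpr, Dio2, Otop1, Ffar4, Cox7a1, Gyk, Tmem171 and Cpt1b, chosen among genes with a mean of at least 5 RPKM, and the fall of each also passed the threshold after centring. Gmpr, a guanosine monophosphate reductase, fell by 4.83 on the log2 scale (SE 0.384, limma adjusted p = 0.000940), and the glycerol kinase Gyk fell by 4.43 (SE 0.219, adjusted p = 0.000209). Otop1, a proton channel, went from 26.3 ± 0.0970 to 0.164 ± 0.0528 RPKM (SD, n = 2 each), and Tmem171 from 21.3 ± 2.33 to 0.109 ± 0.0712 RPKM. Ffar4, a receptor for long-chain fatty acids, fell 28.5-fold. Among the 10 genes with the largest increase were Hsd11b1, Ifi27l2a, Apoc4, Ces1f, Retn, Trf, Lep, Abcd2 and Cfd. Hsd11b1, which regenerates active glucocorticoid, rose 20.2-fold, with a log2 fold change of 3.99 (SE 0.422, adjusted p = 0.00241). The interferon-inducible Ifi27l2a rose 16.1-fold to 759.9 ± 55.9 RPKM and transferrin (Trf) 12.5-fold to 292.2 ± 33.7 RPKM. Cfd, the complement factor adipsin made by fat cells, rose 8.89-fold to 8307 ± 2591 RPKM (SD, n = 2 each).

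Of 30 brown fat and thermogenic genes, 22 fell and 3 rose on RPKM, and 26 fell and 1 rose after centring. Adjusted over the list alone, 25 fell and 4 rose. When Ebf2 KO replicate 2 was left out, 19 fell and 1 rose on RPKM and 23 and 1 after centring. Without Ebf2 KO replicate 1, 1 rose on RPKM, and without WT replicate 2, 0 rose after centring. The list median lay at -3.05 log2 relative to all genes (camera adjusted p = 6.47e-40; adjusted p = 0.172 with an estimated correlation). Ppargc1a, the coactivator of mitochondrial biogenesis, fell 20.5-fold from 16.5 ± 1.08 to 0.806 ± 0.0101 RPKM (SD, n = 2 each), and the nuclear receptor Ppara fell 4.38-fold (limma adjusted p = 0.00732). Prdm16, a coregulator of brown fat identity, was at 0.551 ± 0.00728 RPKM in WT and 0.472 ± 0.0319 in Ebf2 KO (adjusted p = 0.720, and 0.0396 after centring). Its log2 fold change was -0.076 on RPKM and -0.60 after centring. Centring takes the same amount off every gene, also off one this low, which the shift of most genes moves less on this scale. Its fall did not pass in the authors' deposited table (log2 fold change -0.86, edgeR FDR 0.140). The 3 members that rose were the transcription factor gene Lhx8, the transcriptional coregulator gene Cited1 and the F-box gene Fbxo31, named here after their values were seen. Of these only Lhx8, at 1.04 ± 0.170 RPKM in WT and 5.47 ± 1.78 in Ebf2 KO, also rose after centring. The list, like those of the BAF complex and the EBF family, was drawn up with the purpose of the study known, so its direction is not independent evidence.

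Of 25 genes of fatty acid oxidation, 15 fell and 2 rose (17 and 0 after centring; 18 and 3 adjusted over the list alone), with a list median of -1.67 relative to all genes (camera adjusted p = 1.32e-24; adjusted p = 0.172 with an estimated correlation). Cpt1b, which carries long-chain fatty acids into mitochondria, fell 20.5-fold from 226.4 ± 20.1 to 11.04 ± 0.950 RPKM (some of its reads can be shared with a listed readthrough gene that overlaps it), Acaa2 fell 7.69-fold, Etfdh 5.43-fold and Hadhb 5.22-fold. Among the rising members was Cpt1a, the other carnitine palmitoyltransferase isoform, named after its values were seen. Of 19 genes of the tricarboxylic acid cycle and its entry, 16 fell and 1 rose (17 and 0 after centring; 17 and 1 adjusted over the list alone), with a median of -1.75 (camera adjusted p = 1.00e-26; adjusted p = 0.172 with an estimated correlation). Sucla2 fell 7.90-fold, Suclg1 4.64-fold, Idh3a 4.48-fold and Dlst 3.90-fold. The riser, Pcx, named after its values were seen, encodes pyruvate carboxylase, which feeds oxaloacetate to the cycle. Of 55 respiratory chain and ATP synthase subunits, 32 fell and 3 rose (26 and 1 after centring; 42 and 3 adjusted over the list alone), with a median of -1.39 (camera adjusted p = 7.90e-42; adjusted p = 0.196 with an estimated correlation). Cox7a1, a cytochrome oxidase subunit of brown fat and muscle, fell 22.2-fold from 1634 ± 411.0 to 73.7 ± 22.7 RPKM, Cycs 3.62-fold and Uqcrc1 3.24-fold. Atp5g1, which encodes the c subunit of ATP synthase, rose 4.42-fold from 48.2 ± 8.04 to 213.2 ± 11.3 RPKM (SD, n = 2 each; limma adjusted p = 0.00194), and the call held after centring. Atp5g3 and Atp5j, named after their values were seen, rose on RPKM but did not pass after centring. Without Ebf2 KO replicate 2 the falling members numbered 9 of 25, 7 of 19 and 4 of 55 in these lists (8, 7 and 2 after centring). The rising members of the first list were then 0 on RPKM, and 1 on RPKM and 1 after centring without Ebf2 KO replicate 1. The medians without Ebf2 KO replicate 2 were, relative to all genes, -1.43, -1.56 and -1.32. Other libraries moved the respiratory list too. Its falling members were 17 without Ebf2 KO replicate 1 (9 after centring, with 0 rising), 17 without WT replicate 1 and 44 without WT replicate 2 after centring, with medians between -1.15 and -1.56. For the cycle, 11 fell after centring without Ebf2 KO replicate 1. Some genes stood in more than 1 list: Cpt1b, Pdk4, Cox7a1 and Cox8b were also brown fat genes, and Sdha and Sdhb counted under both the cycle and the respiratory chain.

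Of 16 glycolytic genes, 8 fell and 2 rose (9 and 1 after centring; 9 and 3 adjusted over the list alone). The list had a median of -1.20 relative to all genes (camera adjusted p = 3.48e-10; adjusted p = 0.330 with an estimated correlation). With Ebf2 KO replicate 2 left out, 7 fell and 1 rose on RPKM, and 6 and 1 after centring. Without WT replicate 2, 8 fell and 3 rose after centring. Ldhb, a lactate dehydrogenase subunit, fell 7.69-fold, Pgam1 4.81-fold and Pgk1 2.76-fold, and Eno1 fell from 314.3 ± 85.8 to 104.8 ± 5.22 RPKM. The 2 that rose, Eno3 and Pfkm, named after their values were seen, are the isoforms most abundant in skeletal muscle. Of 15 target genes of PPAR alpha, 3 fell and 5 rose (7 and 3 after centring; 7 and 6 adjusted over the list alone). Their counts without Ebf2 KO replicate 2 were 3 and 5 on RPKM and 5 and 4 after centring. The list median of -0.66 relative to all genes (camera adjusted p = 0.000456) lost its call after centring (adjusted p = 0.137) and with quantile normalization (0.124; adjusted p = 0.466 with an estimated correlation). The median was -0.36 without Ebf2 KO replicate 2. Without WT replicate 1 and 2 in turn, 5 and 6 fell on RPKM, and without WT replicate 1 or Ebf2 KO replicate 1, 1 rose after centring. Pdk4, a kinase that shuts off pyruvate dehydrogenase, fell 13.9-fold and the lipid droplet protein Plin2 4.05-fold. The pantetheinase Vnn1 rose from 0.174 ± 0.0462 to 4.59 ± 1.55 RPKM (SD, n = 2 each). Fatty acid synthesis genes went both ways, with 8 of 15 higher and 2 lower on RPKM (6 and 3 after centring; 9 and 2 adjusted over the list alone) and no call for the list (camera adjusted p = 0.679, but 0.00218 without WT replicate 1). The counts without Ebf2 KO replicate 2 were 8 and 2 on RPKM and 7 and 2 after centring. Scd1, a fatty acid desaturase, rose 9.30-fold, Pnpla3 9.72-fold and malic enzyme (Me1) 3.83-fold. The elongase Elovl6 fell 6.27-fold from 10.4 ± 0.110 to 1.67 ± 0.00529 RPKM (SD, n = 2 each).

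Of 15 genes enriched in white fat, 11 were higher and 0 lower (9 and 0 after centring; 13 and 0 adjusted over the list alone). The list median lay at 1.54 relative to all genes (camera adjusted p = 5.47e-05; adjusted p = 0.671 with an estimated correlation). Leaving out Ebf2 KO replicate 2 left 8 higher on RPKM and 7 after centring, and without WT replicate 1 the centred count was 6. Lep went from 1.48 ± 0.209 to 26.2 ± 10.4 RPKM and Retn from 91.4 ± 38.8 to 1108 ± 9.56 RPKM. The amino acid transporter Slc7a10 rose 8.07-fold and angiotensinogen (Agt) 4.17-fold. Of 20 general adipocyte genes, 9 were higher and 0 lower on RPKM, 2 and 2 after centring, and 11 and 3 adjusted over the list alone, with no call for the list (camera adjusted p = 0.679, but 0.0224 without WT replicate 1 and 0.0338 with quantile normalization). Leaving out Ebf2 KO replicate 2 gave 5 and 0 on RPKM and 1 and 0 after centring, and without Ebf2 KO replicate 1 they were 4 and 1, and 0 and 2. Without WT replicate 1 they were 10 and 2, and 2 and 1, and without WT replicate 2 they were 11 and 2, and 0 and 1. Cfd and the adipogenic factor Cebpa, which rose 5.02-fold, kept their calls after centring. Adiponectin (Adipoq) rose 3.63-fold and Cidec 3.29-fold on RPKM (limma adjusted p = 0.00728 and 0.00925), calls that were lost after centring (0.0962 and 0.102). Both calls were also lost by voom on recovered reads (limma adjusted p = 0.117 and 0.15). They held with quantile normalization and in the authors' deposited table (edgeR FDR 0.00826 and 0.0245). The call of Adipoq was also lost without Ebf2 KO replicate 2 (0.0693). Pparg, the master regulator of fat cells, was at 55.3 ± 15.1 RPKM in WT and 33.2 ± 3.03 in Ebf2 KO (adjusted p = 0.0638, and 0.0146 after centring, where its log2 fold change was -1.22). The difference of Pparg also passed without WT replicate 1 (adjusted p = 0.00183).

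Of 19 skeletal muscle markers, 15 were higher and 0 lower (13 and 0 after centring; 17 and 0 adjusted over the list alone), with a median relative to all genes of 1.60 (camera adjusted p = 0.000226; adjusted p = 0.813 with an estimated correlation). Actin (Acta1) was at 336.1 and 843.6 RPKM in the WT libraries and at 3281 and 3118 in the Ebf2 KO libraries. The troponins Tnni2, Tnnc2 and Tnnt3 rose 6.08-fold, 5.92-fold and 5.78-fold. Of 16 fibroblast and adipocyte precursor markers, 15 were higher and 0 lower (10 and 0 after centring; 16 and 0 adjusted over the list alone), with a median of 1.24 (camera adjusted p = 0.000147; adjusted p = 0.813 with an estimated correlation). Among them were Lum (5.90-fold), Dcn (5.07-fold), Mfap5 (5.05-fold) and Col3a1 (4.97-fold). Of 15 macrophage and monocyte markers, 9 were higher and 0 lower (6 and 0 after centring; 13 and 0 adjusted over the list alone), with a median of 0.87 (camera adjusted p = 0.00677; adjusted p = 0.813 with an estimated correlation, and 0.124 at the preset one among genes with a mean of at least 5 RPKM). The genes Mrc1, Fcer1g, Csf1r and Tyrobp rose 4.01-fold, 3.89-fold, 3.79-fold and 3.03-fold. The call of Mrc1 was lost without Ebf2 KO replicate 2 (limma adjusted p = 0.0878), and those of Tyrobp and Col3a1 by voom on recovered reads (0.0508 and 0.0602), that of Tyrobp with quantile normalization too. With Ebf2 KO replicate 2 out, 12, 7 and 3 members of these 3 lists passed on RPKM, and 10, 3 and 7 after centring. Without WT replicate 1, 15, 14 and 6 passed on RPKM, but 3, 1 and 1 after centring, and the muscle median was 0.81 and the macrophage median 0.35. The muscle median was 2.47 without WT replicate 2. The macrophage count was 6 on RPKM and 4 after centring without Ebf2 KO replicate 1, and 10 after centring without WT replicate 2.

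Of 11 endothelial markers none passed on RPKM by limma (1 higher and 0 lower at an unadjusted p under 0.05, and 0 adjusted over the list alone), and 1, Flt1, named after its values were seen, fell after centring and in the authors' deposited table (camera adjusted p = 0.381). Cldn5 was at 185.6 ± 39.8 RPKM in WT and 178.6 ± 5.49 in Ebf2 KO, and Pecam1 at 33.7 ± 10.9 and 36.2 ± 7.75 (SD, n = 2 each). Without WT replicate 2, 5 endothelial markers were higher on RPKM and 0 after centring. None was lower after centring without WT replicate 1, WT replicate 2 or Ebf2 KO replicate 2. Of 11 smooth muscle and mural markers, 6 were higher on RPKM and 2 after centring (6 adjusted over the list alone; camera adjusted p = 0.164, but 0.0185 without WT replicate 2). Desmin (Des) rose 4.44-fold and Myh11 2.66-fold, and Cspg4 and Myl9 rose on RPKM but did not pass after centring. Without Ebf2 KO replicate 2 the calls of Myh11, Cspg4 and Myl9 were lost (limma adjusted p = 0.0899, 0.192 and 0.103), as was that of Cspg4 without WT replicate 1 (0.0606) or Ebf2 KO replicate 1 (0.0739) and that of Myh11 by voom on recovered reads (0.0682). The mural count was 1 on RPKM and 1 after centring without Ebf2 KO replicate 2, 3 and 0 without WT replicate 1, 3 and 1 without Ebf2 KO replicate 1 and 7 and 1 without WT replicate 2. Of 8 Schwann cell and nerve markers, 5 were higher and 1 lower (4 and 1 after centring; 7 and 1 adjusted over the list alone; camera adjusted p = 0.617, but 0.0451 after centring and 0.0173 without WT replicate 2). The myelin gene Pmp22 and the adhesion gene Ncam1 rose on RPKM, whereas S100b fell 14.4-fold from 26.5 ± 3.93 to 1.84 ± 0.974 RPKM. The call of Ncam1 was lost after centring (limma adjusted p = 0.195). It held with quantile normalization, by voom on recovered reads and in the authors' deposited table (edgeR FDR 0.00379). Without WT replicate 1 and without Ebf2 KO replicate 2 it was lost too (log2 fold changes of 0.70 and 0.68, against 0.84 on RPKM). That of Pmp22 was lost with quantile normalization (limma adjusted p = 0.0505) and by voom on recovered reads (0.0626). Leaving out Ebf2 KO replicate 2, 1 of them was higher and 1 lower on RPKM and after centring, and the centred counts were 0 and 1 without WT replicate 1 and 2 and 1 without WT replicate 2. None of the 3 lymphocyte, 7 erythroid or 2 epithelial markers passed the threshold by limma on RPKM (1, 2 and 2 higher at an unadjusted p under 0.05) or after centring. Adjusted over the list alone, 0, 0 and 2 were higher, as in the authors' deposited table. Cd79b was at 0.578 ± 0.533 and 1.29 ± 0.172 RPKM and Krt18 at 0.196 ± 0.1003 and 2.60 ± 2.86. The globin gene Hbb-b1 was at 1095 ± 228.0 and 2620 ± 1899, and Hbb-bs at 1082 ± 225.2 and 2587 ± 1875 (SD, n = 2 each). Both had the same recovered reads in each library (117685, 139996, 441476 and 131159), so they are 1 measurement listed under 2 names. The 7 erythroid entries are thus not all separate measurements, which also holds for the list test (camera adjusted p = 0.629). The erythroid median relative to all genes was 0.60, but 0.83 without WT replicate 2, 1.49 without Ebf2 KO replicate 2 and -0.16 without Ebf2 KO replicate 1. Without WT replicate 2 all 7 erythroid markers and 1 lymphocyte marker were higher on RPKM and 0 after centring, and without WT replicate 1, 2 erythroid markers were higher on RPKM. Both epithelial markers were higher on RPKM when WT replicate 1, WT replicate 2 or Ebf2 KO replicate 2 was left out, and after centring without Ebf2 KO replicate 2.

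**Figure D2:**
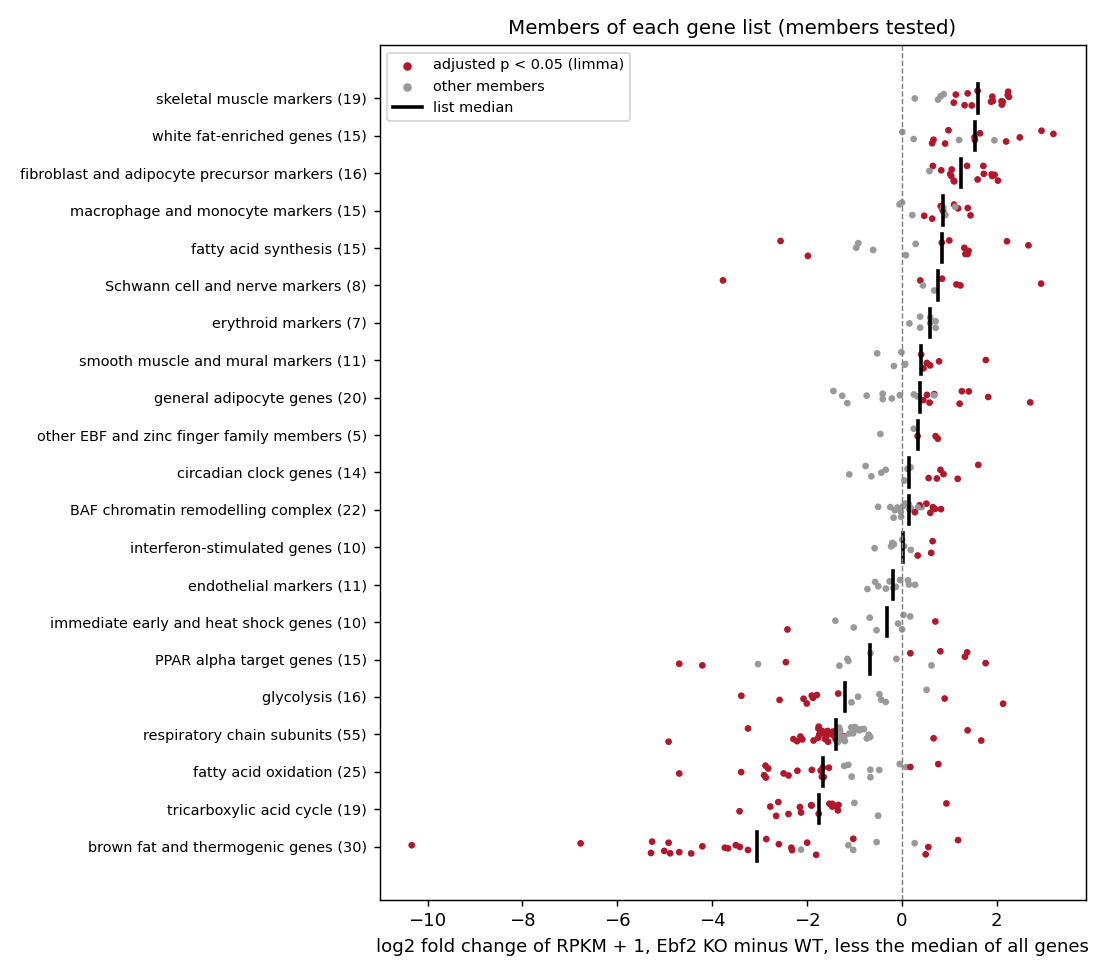
Log2 fold change of RPKM + 1 (Ebf2 KO minus WT) less the median of all genes, on the horizontal axis, for each member of the 21 gene lists with at least 5 members; red points passed an adjusted p under 0.05 by limma on RPKM, grey points did not, and each black bar is the list median. List medians ran from -3.05 for brown fat and thermogenic genes to 1.60 for skeletal muscle markers, and endothelial markers lay at -0.18.

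Of 22 genes of the BAF chromatin remodelling complex, 7 were higher on RPKM (8 adjusted over the list alone) and 0 after centring. No gene was lower in either, with no call for the list (camera adjusted p = 0.144). By limma at an unadjusted p under 0.05, 4 were higher and 1 lower after centring. Past the adjusted threshold, 0 were higher by voom on recovered reads and 1 in the authors' deposited table. Without Ebf2 KO replicate 2, 1 was higher on RPKM, against 3 without WT replicate 1, 4 without Ebf2 KO replicate 1 and 11 without WT replicate 2. The subunit genes Bcl7c, Smarcd3, Smarcc2 and Arid1a were 2.53, 2.22, 2.38 and 2.44 times higher on RPKM, differences that did not pass after centring (limma adjusted p = 0.0786, 0.163, 0.0735 and 0.128). Without Ebf2 KO replicate 2, Smarcd3, Smarcc2 and Arid1a did not pass on RPKM (0.0716, 0.0951 and 0.2002), nor did Arid1a without WT replicate 1 (0.0659) or Ebf2 KO replicate 1 (0.0859), and Dpf3 was not analysed here. Of 5 other EBF and zinc finger family genes, 3 were higher on RPKM (4 adjusted over the list alone) and 0 after centring, when 2 were higher and 1 lower at an unadjusted p under 0.05 by limma (camera adjusted p = 0.329), and 2 were higher by voom on recovered reads and 2 in the authors' deposited table. None was higher on RPKM without Ebf2 KO replicate 2. After centring, 1 was higher without WT replicate 1 and 1 lower without WT replicate 2. Ebf1 was at 5.25 ± 1.64 RPKM in WT and 13.3 ± 0.867 in Ebf2 KO. Zfp423 was at 1.41 ± 0.122 and 4.43 ± 0.403, and Zfp521 at 0.315 ± 0.149 and 1.27 ± 0.318 (SD, n = 2 each). Without Ebf2 KO replicate 2 their adjusted p by limma was 0.0571, 0.110 and 0.150, that of Ebf1 was 0.0502 without Ebf2 KO replicate 1, and that of Zfp521 was 0.0720 without WT replicate 1.

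Genes that respond to handling, interferon or the time of day were read as well. Of 10 immediate early and heat shock genes, the stress-induced factor Atf3 fell 5.37-fold and Zfp36 rose on RPKM but did not pass after centring, and 3 fell after centring (2 lower and 2 higher adjusted over the list alone; camera adjusted p = 0.0676, but 0.0146 without WT replicate 1 and 0.0265 without Ebf2 KO replicate 1). Of 10 interferon-stimulated genes, 3, among them Bst2 and Irf7, were higher on RPKM and none after centring, when 1, Usp18, named after its values were seen, was lower (3 higher adjusted over the list alone; camera adjusted p = 0.679). In the authors' deposited table none of this list was higher or lower. Of 14 circadian clock genes, 6 were higher and 0 lower, or 5 and 3 after centring (6 and 0 adjusted over the list alone; camera adjusted p = 0.693). Nr1d1, a repressor of the clock, rose 4.64-fold, Cry2 2.81-fold, Dbp 3.50-fold and Tef 2.62-fold. The call of Tef was lost with quantile normalization (limma adjusted p = 0.0510), by voom on recovered reads (0.0759), without Ebf2 KO replicate 2 (0.0832) and in the authors' deposited table (0.0536). That of Dbp was lost with quantile normalization and by voom (0.0537 and 0.0566), and that of Cry2 by voom. The calls of Zfp36, Bst2 and Irf7 were lost without Ebf2 KO replicate 2 (0.0881, 0.0855 and 0.233), and that of Irf7 also without WT replicate 1 (0.128) or Ebf2 KO replicate 1 (0.0539). For Ebf2 KO replicate 1 alone against WT, the higher and lower members were 0 and 1 of the immediate early list, 0 and 0 of the interferon list and 3 and 0 of the clock list on RPKM. Without WT replicate 1 these were 1 and 3, 1 and 0, and 5 and 1. After centring no interferon gene was lower without WT replicate 1 or Ebf2 KO replicate 2. The clock list had 0 and 0 after centring without WT replicate 1, 3 and 2 without WT replicate 2, 2 and 0 without Ebf2 KO replicate 2 and 2 and 3 without Ebf2 KO replicate 1. With 2 libraries a group the p-values rest on the spread between these libraries and on the variance that limma borrows from other genes. Of the named genes, all 31 that fell passed the threshold on RPKM without each library in turn, whereas 35 of the 54 that rose did so. After centring, 29 and 17 did so. On RPKM the remaining 19 all lost their call without Ebf2 KO replicate 2.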

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

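The tests on recovered reads and all combinations with median centring were chosen after the result was seen. The counts of genes higher and lower moved with the scaling: 1048 and 1010 with quantile normalization, 1024 and 1253 with median centring, 979 and 1034 by voom on recovered reads and 1325 and 1277 in the authors' deposited table. A mean of at least 5 RPKM gave 1717 higher among fewer genes. Stricter thresholds gave 565 and 145 at an adjusted p under 0.01, and 1736 and 280 at an absolute log2 fold change of at least 1 (609 and 717 after centring). Leaving out single libraries gave 810 to 4477 higher and 166 to 561 lower, and 415 to 904 and 578 to 1094 after centring; with 1 library left in a group, that library is assumed to vary like the other group. Nothing states that replicate numbers pair the libraries. Replicate 1's deviations from the group means correlated at r = 0.348 across genes between the genotypes, and the replicate block gave 6325 higher and 746 lower, or 1781 and 2411 after centring. Of the 21 lists, camera called 10 at the preset correlation and 0 with an estimated correlation (4 at an unadjusted p under 0.05); fry called 4, and 0 on centred values (8 at an unadjusted p under 0.05). Fry asks whether a list moves one way, not whether it differs from other genes. With 1 choice of the fit changed at a time and an adjusted p under 0.05, Ebf2 kept its call wherever it had a value, with log2 fold changes from -3.58 to -1.40, as did 31 of 31 named genes that fell and 28 of 54 that rose. After centring without each library these were 29 and 17, and at an adjusted p under 0.01 they were 31 and 30. The minimum mean of 5 RPKM left out Ebf2, Ppara and other low genes, so it tested none of these. Signs turned for 3 genes that passed no threshold on RPKM. Pecam1 was at -0.37 with quantile normalization, -0.40 with centring, -0.54 by voom and -0.52 in the authors' deposited table, and ran from -0.21 to 0.45 without single libraries; Ptprc was at -0.0213 with centring; Cldn5 ran from -0.26 to 0.18 without single libraries. The cause of these moves was not tested beyond the scaling. No filter on low values equals the values used, since the table already holds only genes above 0.5 RPKM, and the alternatives planned for counts were not run because the values are RPKM. Depth limited few genes named here, since 1 read of a 1 kb gene was worth at most 0.00614 RPKM.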

Other observations

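All gene families and tests in this part were chosen after the result was seen. All 8 measured insulin-like growth factors and their binding proteins rose on RPKM (6 after centring), with a median of 1.17 relative to all genes (camera adjusted p = 0.000284; adjusted p = 0.473 with an estimated correlation). Igf1, a growth factor, went from 5.755 ± 0.502 to 42.8 ± 0.335 RPKM and Igf2 from 112.4 ± 46.2 to 412.7 ± 36.1 (SD, n = 2 each). All 8 complement components rose, also after centring (median 1.46, camera adjusted p = 0.000760; adjusted p = 0.473 with an estimated correlation). C1qa went from 19.9 ± 10.1 to 79.4 ± 6.49 RPKM and C3 from 19.5 ± 7.05 to 78.0 ± 28.2. Of 9 apolipoprotein genes 7 rose (5 after centring; median 1.62, camera adjusted p = 0.000451; adjusted p = 0.473 with an estimated correlation). Apoe went from 429.1 ± 38.05 to 3786 ± 2047 RPKM. Of 13 class I histocompatibility genes, which present antigen and share sequence so that reads can be split between them, 10 rose (4 after centring; median 0.89, camera adjusted p = 0.00318; adjusted p = 0.473 with an estimated correlation). Their partner B2m, which is counted among these 13, went from 159.2 ± 35.9 to 1053 ± 22.4 RPKM. Of 22 collagen genes 13 rose and Col27a1 fell (10 rose and 2 fell after centring; camera adjusted p = 0.0316; adjusted p = 0.667 with an estimated correlation). Of 7 mast cell genes 5 rose, also after centring (median 1.86, camera adjusted p = 0.00564; adjusted p = 0.473 with an estimated correlation). The tryptase Tpsab1 went from 4.53 ± 1.67 to 35.0 ± 1.59 RPKM and Cpa3 from 10.2 ± 6.89 to 54.6 ± 13.3.

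Of 77 mitochondrial ribosomal protein genes, 7 fell and 1 rose on RPKM and 20 fell and 0 rose after centring, with a median of -0.61 relative to all genes (camera adjusted p = 1.03e-15; adjusted p = 0.473 with an estimated correlation). Mrps36, counted in this family by its symbol as all members were, went from 151.6 ± 5.29 to 40.04 ± 1.56 RPKM (SD, n = 2 each). Of 24 mitochondrial import genes 4 fell and 3 rose, or 6 and 0 after centring (median -0.52, camera adjusted p = 4.02e-05; adjusted p = 0.473 with an estimated correlation). The 82 cytosolic ribosomal protein genes had a median of 0.23 relative to all genes, with 16 higher on RPKM and 2 higher and 1 lower after centring (camera adjusted p = 0.00786; adjusted p = 0.686 with an estimated correlation). Their median log2 fold change itself was 0.69 on RPKM, 0.44 with quantile normalization, 0.16 after centring and 0.02 by voom on recovered reads. Of 10 genes of the integrated stress response, the programme that ATF4 drives, 3 fell on RPKM and 8 after centring (median -1.88, camera adjusted p = 4.09e-10; adjusted p = 0.473 with an estimated correlation). Atf4 went from 154.0 ± 47.6 to 56.0 ± 5.66 RPKM and Ddit3 from 63.6 ± 47.9 to 16.1 ± 0.365. Between the Ebf2 KO libraries, 18 genes with a mean of at least 5 RPKM differed over 4-fold. Among them the imprinted genes Mest (58.7 and 411.6 RPKM in replicates 1 and 2), its neighbour Copg2 (43.6 and 269.2) and Nnat (163.3 and 1102) were higher in replicate 2. Stfa1, which differed most (0.108 and 22.4), was higher in replicate 2 as well, whereas the neutrophil gene S100a9 (117.8 and 26.2) was higher in replicate 1.

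RPKM of most genes was higher in Ebf2 KO: over 10365 genes the median log2 ratio of the 4 library pairs ran from 0.37 to 0.89, with a mean of 0.63. Scaling each library to its reads in the listed genes gave a mean of 0.181, but the drop of 0.38 to 0.52 is by construction the log2 ratio of the libraries' shares of reads in listed genes, so it does not test what lies behind the shift. The 50 most abundant genes of each library held 20.1% and 19.02% of the reads in listed genes in the WT libraries and 21.1% and 19.2% in the Ebf2 KO libraries, and also leaving the 50 most abundant in any library out of the totals gave a mean of 0.187, which argues against a larger share of a few listed genes in WT. The effect of reads outside the listed genes, and of mitochondrially encoded transcripts among them, cannot be told apart from other sources, since those reads were not measured and 0 such transcripts were listed. Whether part of the shift is biological was not tested.

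Skeletal muscle markers were higher in Ebf2 KO in each of the 4 pairs, by a median of 0.82 to 2.47 relative to all genes. A lower share of brown fat cells that raised all other cell types alike would raise endothelial markers as much as muscle markers. Relative to all genes, the endothelial median ran from -0.45 to 0.00. Its level alone does not show that these markers did not rise, since their median log2 fold change on RPKM was 0.28. The muscle median exceeded the endothelial one by at least 1.27 and at most 2.46, which argues against an equal rise of all other cell types. The fibroblast and macrophage medians also lay above all genes, at 1.24 and 0.87. A lower share of brown fat cells with endothelial cells falling alongside was not tested and stays open. All 19 markers were higher in WT replicate 2 than in WT replicate 1, by a median of 1.20, so varying amounts of muscle in the tissue pieces may account for part of the pattern; between the Ebf2 KO libraries the median was 0.05. An effect of the genotype on muscle genes cannot be told apart from dissection, because the smallest pair still differed by 0.824 and no muscle-free sample was measured.

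Cidea, and Cox8b, a cytochrome oxidase subunit of brown fat chosen after its values were seen, were higher in Ebf2 KO replicate 1 (63.5 and 816.4 RPKM) than in replicate 2 (3.81 and 263.5). Carry-over of WT tissue would need a WT share of 4.26% for Cidea and 18.7% for Cox8b, but Ucp1 allows 0.0843%. The share for Cidea would bring Ucp1 to 231.7 RPKM, where 7.39 was measured, and 15 of 20 other brown fat genes that fell lay below that share. These values argue against carry-over as the cause. A difference in sex between the knockout mice may contribute, since Xist was at 0.0353 RPKM in replicate 2 against 5.49 in replicate 1. The labels do not give the sex, and no Y-linked gene was analysed here. With 1 knockout library at each Xist level, sex cannot be told apart from other differences between these libraries.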
